A study of Mus musculus with 15 samples.

How the data were processed

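Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 15 organoid lines of mouse colon cancer grown from liver metastases or primary tumours of transplanted C57Bl6 mice. The genotype is labelled AKP. Per the labels' protocols, the libraries were made from dissociated organoid cells with the TDE1 enzyme and sequenced in paired-end mode. The submitters' processing notes name Bowtie, Picard, SAMtools, MACS2 and bedtools and the genome build mm9, with no roles, order or versions. Whether the authors shifted reads for the transposase offset, removed duplicates or excluded mitochondrial reads is not given in the sources used here.

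The deposited table holds whole-number counts per region and library for 43020 regions, which the authors named as called over all samples together. Each region's name carries a score by the authors, of a scale that is not given in the sources used here, with a lowest value of 5.00015. The score was used only to describe regions. Regions were 200 to 6777 bp wide (median 746 bp), and each held at least 20 counts over the 15 libraries. A shared region set means that the same intervals were counted in every line, and that a region open in few lines had less weight when regions were called. Coordinates are those of the table, in mm9.

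Groups and replicate numbers were taken from the sample titles. Met1, Met2 and Met3 are lines from liver metastases of transplantation rounds 1, 2 and 3, and Primary2 and Primary3 are lines from primary tumours of rounds 2 and 3, with 3 lines in each group. Primary lines of round 1 were not analysed here. Per the series' design text the lines are separate organoid lines. Which line descended from which is not given in the sources used here, so p-values measure only the spread among these lines.

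Counts were tested per region with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Regions were kept by filterByExpr (minimum count 10, minimum total count 15), which left 39952 regions, 92.9% of the table. Libraries were scaled by TMM, and a single quasi-likelihood model with 5 group means and robust dispersion was fitted to all 15 libraries, so that the groups shared an estimate of the spread. Regions were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken from the fold change and the F statistic. CPM values are counts scaled to a common library size after TMM, and log2 CPM used a prior count of 2. Fold changes came from the fit, with edgeR's default prior count and not this value. The contrasts were metastasis against primary in rounds 2 and 3 together (the mean of both rounds' differences), in each round alone, the difference between the rounds, later metastasis groups against Met1, Met3 against Met2 and Primary3 against Primary2. A contrast of Met1 with the mean of the primary groups was looked at while exploring and is not used here.

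For chromosome-wide shifts, each library's median over the regions of a chromosome was taken of log2 CPM minus the mean of the 15 libraries, relative to the library's own median over all regions. Metastasis and primary lines of rounds 2 and 3 were compared by a 2-sided exact permutation test within rounds (400 assignments, smallest p 0.005), adjusted over 20 chromosomes without Y.

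The tests, contrasts, main alternatives and the rule for naming regions were fixed before the data were examined. The rule took, in rounds 2 and 3 together, the 8 regions with the largest and the 8 with the smallest log2 fold change among those called, with mean log2 CPM at or above the median of tested regions and every metastasis line above (or below) every primary line of its round. It took 3 per direction by the same rule in round 2, in round 3 and in Met3 against Met1.

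On simulated counts for the 39952 regions, the comparison of rounds 2 and 3 together recovered 42 of 100 regions changed 2-fold and 96 of 100 changed 4-fold, and 2.82% of its calls were false. Round 2 alone recovered 14 of 100 and 72 of 100, with 3.37% false. The changed regions all had at least the median signal, and noise was drawn independently for each region and line. Far fewer regions were changed than the 8080 called in the data for rounds 2 and 3 together. Recovery and the share of false calls in the data can therefore differ. A planted chromosome shift of 0.30 on the log2 scale was recovered as 0.27.

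Alternatives were DESeq2 1.42.0 size factors and its Wald test, scaling by total counts, no filter and a stricter filter, a fit of only the groups compared, the replicate number as a block, removal of each library's chromosome medians, removal of a lowess trend on mean signal (span 0.3), and leaving out each replicate in turn. Further computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

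Library totals ran from 285633 to 5916109 counts. In the shallowest library, Primary3 replicate 2, the median region held 4 counts and 10020 regions held 0, so its single-region values are imprecise. Met1 replicate 1, with 790233 counts, had a flatter profile, with 25.2% of its counts in the tenth of regions with the highest scores. The other 14 libraries had between 31.0% and 35.3% there.

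Regions were not assigned to genes. The gene table used here is of another build than mm9, coordinates were not converted, and no genome sequence of mm9 was used here. The planned gene list tests, markers of other cell types, motif enrichment and GC-content offsets were therefore not run, and regions are named by position.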

Results

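Chromatin accessibility was profiled in 15 colon cancer organoid lines, 3 in each of 5 groups, to follow lines from liver metastases and from primary tumours through serial transplantation into the colon. The counts in regions summed to 790233, 3161464 and 3342414 in the Met1 libraries, 1562332, 2279533 and 1469502 in Met2, and 1777563, 2797725 and 1588088 in Met3. The Primary2 libraries held 1737791, 1823141 and 1235330 counts, and the Primary3 libraries 3051139, 285633 and 5916109. The lines of a group varied most in Met2 (biological coefficient of variation 0.442) and Met1 (0.37) and least in Primary2 (0.247). Within Met2, replicate 1 correlated with replicates 2 and 3 at r = 0.743 and 0.692 across regions, whereas replicates 2 and 3 correlated at 0.844. Met2 replicate 1 correlated about as well with Met1 replicates 2 and 3 (0.742 and 0.748), though less with Met1 replicate 1 (0.638). The shallowest line of Met1, replicate 1, correlated with the others at 0.723 and 0.719 (0.897 between these), and that of Primary3, replicate 2, at 0.719 and 0.732 (0.929 between these).

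The first question was which regions differed between metastasis and primary lines in the rounds that held both. In rounds 2 and 3 together, 8080 of 39952 regions (20.2%) changed, of which 4491 were more accessible and 3589 less accessible in metastasis lines (edgeR quasi-likelihood test). Scaling by total counts gave a more even split, with 4126 higher and 4026 lower. At least 4-fold changes were found in 1153 of the higher and 675 of the lower regions. Regions are named among those called with at least the median signal and with every metastasis line above, or below, every primary line of its round. Of these, the largest increase was at peak_66890 (mm9 chromosome 4, 117804698 to 117805278), with 35.0 ± 9.63 CPM in Met2 against 0.772 ± 1.34 in Primary2 and 57.2 ± 17.8 in Met3 against 1.55 ± 2.11 in Primary3 (SD, n = 3 each). Its log2 fold change was 4.92 ± 0.51 (SE, edgeR adjusted p = 8.83e-07). This size rests on a primary group near 0, with 4 reads in Primary2, and was 5.84 without Primary3 replicate 3. Without Primary2 replicate 1, whose 4 reads were the only ones in that group, the fitted value of 6.88 depends on edgeR's default prior count. The largest decrease was at peak_12379 (chromosome 11, 54021960 to 54023278), with 2.37 ± 2.1 CPM in Met2 against 59.8 ± 21.1 in Primary2 and 2.79 ± 1.3 in Met3 against 45.8 ± 7.27 in Primary3, a log2 fold change of -4.25 ± 0.42 (edgeR adjusted p = 6.11e-07).

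The other regions with the largest increases were peak_19674 on chromosome 12 (50244516 to 50245484, log2 fold change 4.80), peak_74058 on chromosome 5 (82033720 to 82034319, 4.46) and peak_6674 on chromosome 10 (21799804 to 21800525, 4.39). They also included peak_30770 on chromosome 15 (15291646 to 15292464, 4.32), peak_36437 on chromosome 16 (26421943 to 26422683, 4.19), peak_10512 on chromosome 11 (4705945 to 4706759, 4.13) and peak_6901 on chromosome 10 (31797306 to 31797920, 4.09). Among decreases, peak_80765 on chromosome 6 (31098423 to 31099814) fell by 4.08 on the log2 scale, peak_9444 on chromosome 10 (98550227 to 98551064) fell by 4.01 and peak_74007 on chromosome 5 (77813000 to 77814422) fell by 4.0. Next came peak_45415 on chromosome 18 (44888369 to 44889383, log2 fold change -3.89), peak_60661 on chromosome 3 (78791716 to 78793595, -3.77), peak_82217 on chromosome 6 (55288980 to 55289601, -3.68) and peak_45343 on chromosome 18 (42929735 to 42931137, -3.64), both far beyond the shift of chromosome 18 as a whole (-0.42). Their standard errors lay between 0.36 and 0.55. The fold changes above compare rounds 2 and 3 and leave out Met1. At each named increase the Met1 mean lay below those of Met2 and Met3, from 0.91 CPM at peak_74058 to 10.1 at peak_10512. At each named decrease it lay between the later metastasis and the primary means, from 5.23 CPM (peak_9444) to 71.6 (peak_80765). At peak_80765 the Met1 lines varied widely (SD 54.5), and Primary3 held 77.3 CPM. The sizes of the increases thus apply to the later metastasis lines and not to Met1.

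**Figure D1:**
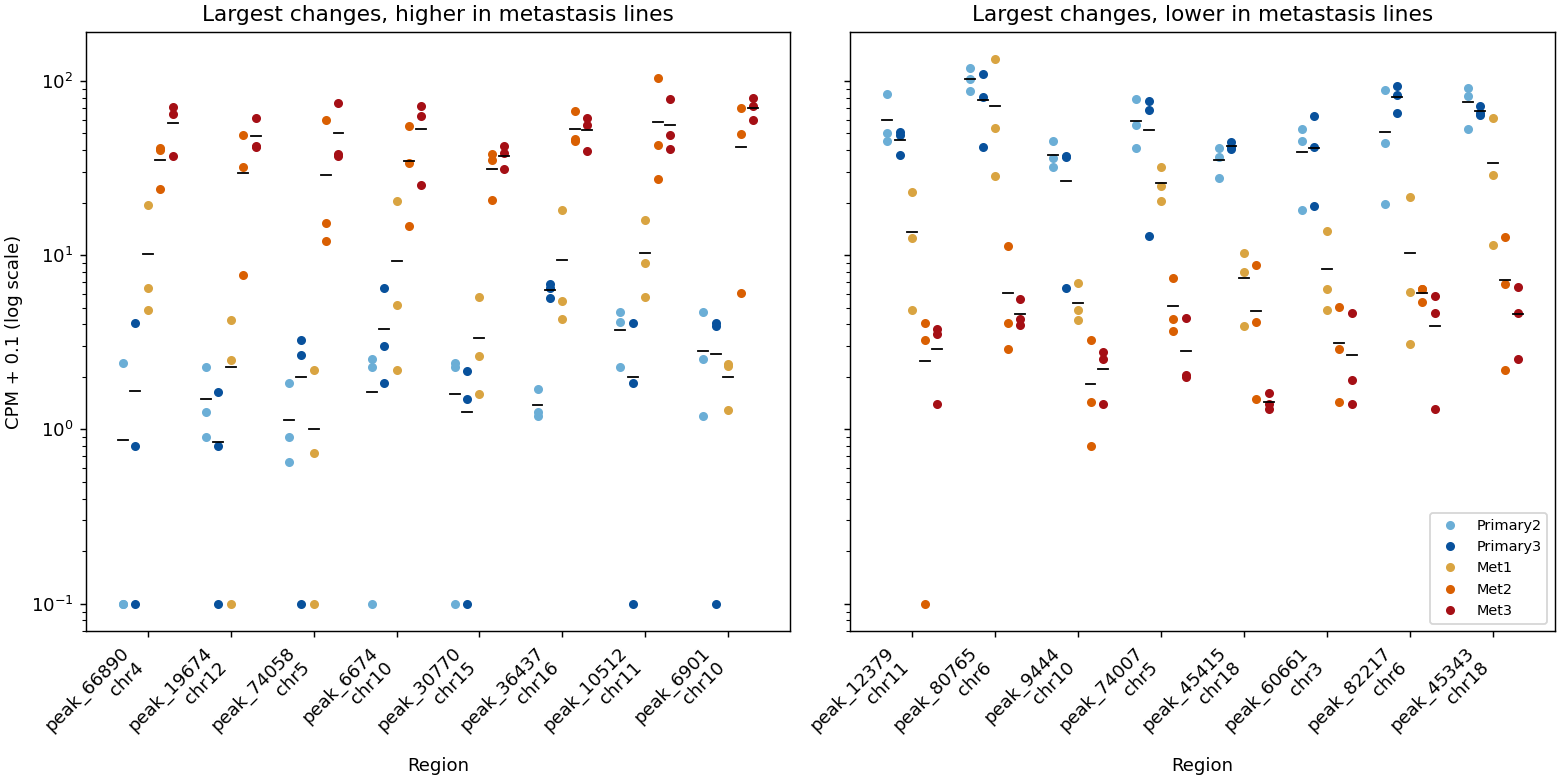
CPM plus 0.1 (log axis) of the 16 regions with the largest changes in rounds 2 and 3 together; each point is a line, and each black bar is the mean of the 3 lines of a group. Met2 and Met3 lines lie apart from the primary lines of their round, as at peak_36437 with 52.8 CPM in Met2 against 1.29 in Primary2.

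In round 2 alone, 2480 regions changed, 1375 higher and 1105 lower in Met2 than in Primary2. By the same criteria the largest increases were at peak_36437 (log2 fold change 5.33 ± 0.55 SE, edgeR adjusted p = 3.13e-05), at peak_66890 (5.31 ± 0.79) and at peak_6971 on chromosome 10 (39150316 to 39151311, 4.89 ± 0.68). The largest decreases were at peak_12379 (-4.57 ± 0.60), at peak_9444 (-4.29 ± 0.58) and at peak_12378, which lies beside peak_12379 on chromosome 11 (54020046 to 54020915, -4.04 ± 0.48). Without Primary2 replicate 1 the other Primary2 lines were at 0 at peak_66890, and the fitted value of 9.25 depends on edgeR's default prior count. Without Primary2 replicate 2 the value was 4.69 there and 5.60 at peak_6971. Without Met2 replicate 2 it was -5.11 at peak_9444. The count depended on the Primary2 lines, with 963, 1103 and 1166 regions without replicates 1, 2 and 3, and a fit of only Met2 and Primary2 called 1315 (657 higher and 658 lower).

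In round 3 alone, 4059 regions changed, 2252 higher and 1807 lower in Met3 than in Primary3. By the same criteria the largest increases were at peak_19674 (log2 fold change 5.32 ± 0.72 SE, edgeR adjusted p = 9.79e-05), at peak_473 on chromosome 1 (31657365 to 31658317, 4.70 ± 0.53) and at peak_47439 on chromosome 18 (83714727 to 83715319, 4.70 ± 0.66). At peak_473 the signal was 116.2 ± 6.22 CPM in Met3 and 4.96 ± 1.23 in Primary3 (SD, n = 3). The largest decreases were at peak_45415 (-4.89 ± 0.56), at peak_74007 (-4.43 ± 0.52) and at peak_53629 on chromosome 2 (65031088 to 65031657, -4.31 ± 0.68). Without Primary3 replicate 3 the value at peak_19674 was 6.14. The excess of higher over lower regions rested on the scaling and the libraries, with 2023 higher and 2076 lower by total counts, 2197 and 2202 with a trend on mean signal removed, and 2089 and 2107 without the 2 shallowest libraries. The count fell to 1831 and 2644 without Met3 replicates 1 and 2 and to 1483 and 1950 without Primary3 replicates 1 and 3.

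Rounds 2 and 3 share no library, so their changes could be compared. The agreement is not an independent replication, since both contrasts came from a single fit and which line descended from which is not known. Differences inherited along the series could recur in both rounds. Of the 2480 regions called in round 2, 2410 (97.2%) had a fold change of the same sign in round 3, called or not, against 68.0% of all tested regions. Both rounds called 719 regions higher, against 77.5 for independent lists, and 615 lower, against 50.0, and 1 region was called in opposite directions. Across the 39952 regions, which are not independent replicates, the log2 fold changes correlated at r = 0.63 (Spearman's rho 0.549). The difference of the metastasis effect between the rounds was called at 0 regions by edgeR, with 2568 regions at an unadjusted p under 0.05, and at 15 by DESeq2.

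**Figure D2:**
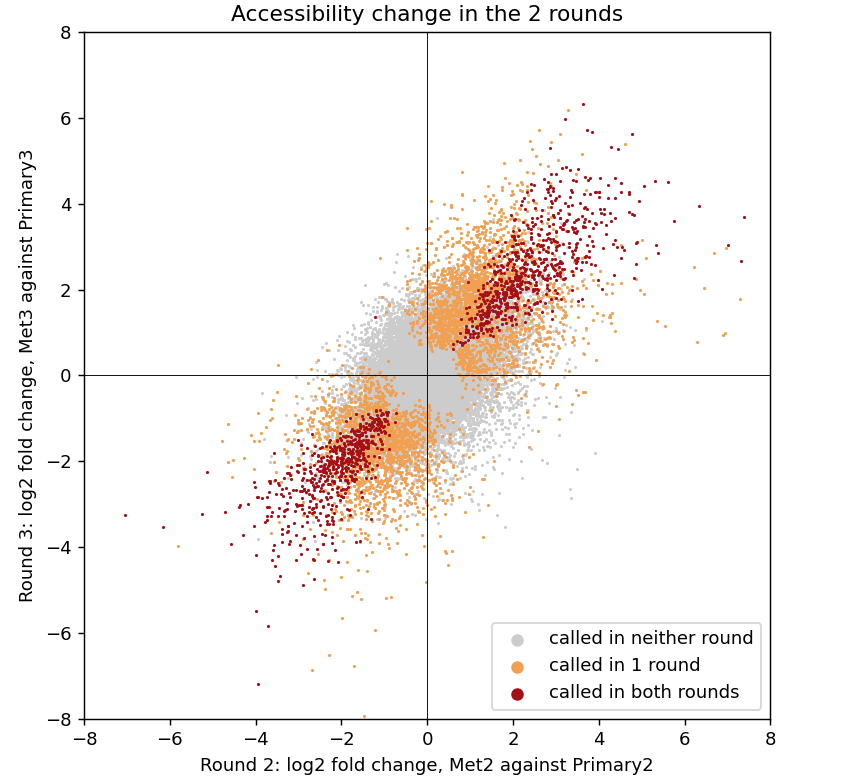
Log2 fold change of each tested region in round 2 (Met2 against Primary2, horizontal) and round 3 (Met3 against Primary3, vertical); each point is a region, coloured by the number of rounds in which it was called. Regions called in both rounds lie in the upper right (719) and lower left (615), except for 1.

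The metastasis lines of round 1 were compared with those of later rounds to see whether accessibility changed along the series. Primary lines of round 1 were not analysed here. Between Met3 and Met1, 3813 regions changed, 2389 higher and 1424 lower in Met3. By the same criteria, the largest increase was at peak_27826 on chromosome 14 (37275379 to 37276091), which rose from 2.53 ± 1.75 CPM in Met1 to 92.1 ± 18.8 in Met3 (SD, n = 3), a log2 fold change of 5.49 ± 0.42 (SE, edgeR adjusted p = 1.27e-07). Next were peak_74058 (5.35 ± 0.71) and peak_6901 (5.25 ± 0.67). Both were also among the largest increases over primary lines, a comparison that shares the Met3 lines. The largest decreases were at peak_56017 on chromosome 2 (132023635 to 132024417, -4.49 ± 0.77), at peak_105208 on chromosome 9 (116117067 to 116118011, -4.27 ± 0.59) and at peak_63072 on chromosome 3 (131677474 to 131678197, -4.13 ± 0.94). At peak_56017, Met1 held 53.4 ± 14.3 CPM and the other groups had means between 2.12 and 9.21. Without Met1 replicate 3, peak_63072 was no longer called (log2 fold change -3.36) and the value at peak_74058 was 6.53. Without Met3 replicate 2 the value at peak_63072 was -5.43, and without Met3 replicate 3 that at peak_56017 was -5.18. The count fell to 2025 and 1940 without Met1 replicates 2 and 3 and to 1852, 2254 and 2516 without Met3 replicates 1, 2 and 3. Scaling by total counts called 50.6% of changed regions higher, against 62.7% with TMM, and moved the median of all regions from -0.04 to -0.17.

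Between Met2 and Met1, 1417 regions changed, 1054 higher and 363 lower in Met2. At peak_27826 the signal was 44.9 ± 11.7 CPM in Met2 (SD, n = 3), a log2 fold change of 4.45 over Met1 (edgeR adjusted p = 1.0e-05), and peak_74058 (4.54) and peak_6901 (4.50) were higher as well. Of the regions with the largest decreases in Met3, peak_56017 (-2.58) and peak_105208 (-2.12) were also called lower in Met2, whereas peak_63072 (-1.51) was not called. These regions were picked for their difference between Met3 and the same Met1 lines, so their recurrence in Met2 is not independent. The count depended on the fit and on single lines. A fit of only these groups called 58 regions, and 561, 475 and 727 were called without Met1 replicate 2, Met1 replicate 3 and Met2 replicate 3. In contrast, 2475 were called without Met2 replicate 1, the line that correlated about as well with Met1 replicates 2 and 3 as with its own group.

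In the fit of all groups, later groups of the same origin differed less. Between Met3 and Met2, edgeR called 0 regions, with 2926 at an unadjusted p under 0.05, and DESeq2 called 44. Between Primary3 and Primary2, edgeR called 0, with 2646 at an unadjusted p under 0.05, and DESeq2 called 54. The count between Met3 and Met2 was 54 without Met2 replicate 2, 45 without Met2 replicate 3 and 1 without Met3 replicate 3. A fit of only the primary groups called 34 regions, and 7 were called without Primary2 replicate 3. The 34 were near the 58 that a fit of only Met2 and Met1 called.

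Chromosomes also differed in their median signal, so part of the regional changes moved with the chromosome they lie on. Chromosome 18 was lower in metastasis lines, at -0.16 ± 0.02 on the log2 scale against 0.26 ± 0.07 in primary lines of rounds 2 and 3 (SD, n = 6 each). Chromosome 8 was lower as well, at -0.13 ± 0.03 against 0.19 ± 0.11. Chromosomes 1 (0.11 ± 0.06 against -0.14 ± 0.04) and 13 (0.09 ± 0.03 against -0.14 ± 0.04) were higher in metastasis lines. The 3 Met1 lines lay between -0.18 and -0.13 on chromosome 18, on the side of the later metastasis lines. Of 20 chromosomes, 10 passed the exact permutation test within rounds, 4 higher (1, 9, 10 and 13) and 6 lower (2, 3, 8, 11, 17 and 18) in metastasis lines, with adjusted p between 0.0125 and 0.04. On chromosomes 1, 2, 8, 9, 11, 13, 17 and 18 the p of 0.005 was the smallest the design can give. In round 3, chromosome 3 was low mainly in Met3 replicate 3 (-0.264). The other Met3 lines (-0.048 and -0.009) overlapped the Primary3 lines (0.044, -0.062 and 0.09). The chromosome still passed with Met3 replicate 3 left out. Chromosome 3 (-0.14) no longer passed without Primary2 replicate 1 (-0.15) or 3 (-0.15) or Primary3 replicate 1 (-0.14) or 3 (-0.13). Chromosome 10 (0.18) did not without Met2 replicate 2 (0.17), Primary2 replicate 3 (0.17), Met3 replicate 1 (0.17) or 2 (0.15) or Primary3 replicate 2 (0.17), with fewer assignments in each case. Not each of these was a shift of the whole chromosome. All 9 windows of 10 Mb on chromosome 18 (-0.833 to -0.065) and all 14 on chromosome 8 (-1.591 to -0.023) were lower. All 12 on chromosome 13 were higher (0.059 to 0.599). On chromosome 17, however, 5 were lower and 5 higher, and on chromosome 9 10 were higher and the last 3 were lower, mainly through the Met3 lines. In the window from 100000001 these stood at -0.36, -0.36 and -0.54, while the Met2 lines (0.20, -0.06 and 0.24) were not below the Primary2 lines (0.02, -0.02 and 0.08) as a group. Of called regions on chromosome 18, 73 were higher and 343 lower, and on chromosome 5, which varied from line to line, 392 were higher and 93 lower. With each library's chromosome medians removed, 7488 regions were called in rounds 2 and 3 together, 6545 of them shared with the 8080.

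**Figure D3:**
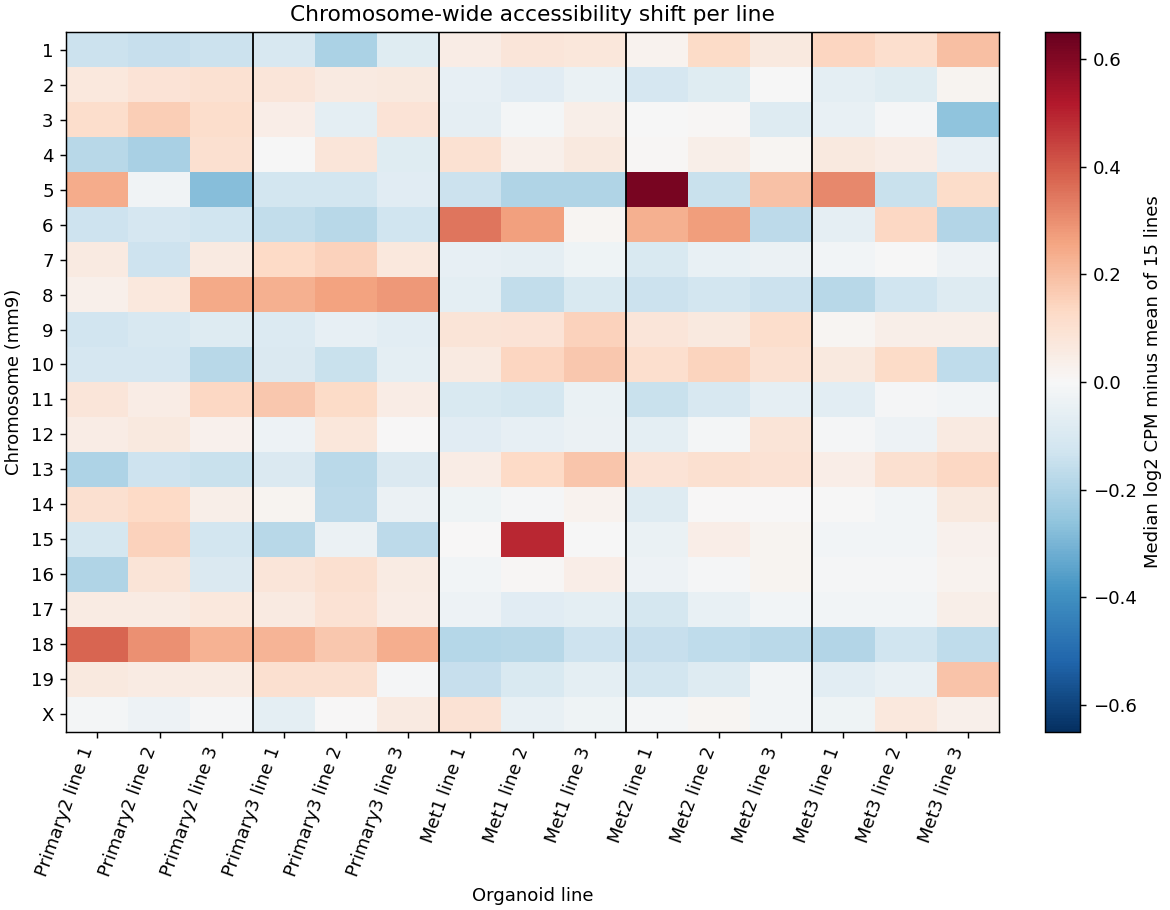
Median log2 CPM of the regions of each chromosome (rows, mm9) minus the mean of the 15 lines, for each organoid line (columns, groups parted by black lines). Chromosome 18 is higher in all 6 primary lines than in all 9 metastasis lines, and a single line stands apart on chromosome 15 (0.49 in Met1 replicate 2). Chromosome 5 varies from line to line, with its highest value in Met2 replicate 1 (0.62), which the test of each line's distance did not single out.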

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

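The test of each line's distance from the others on a chromosome was set in advance, and the counts of 10 Mb windows given beside it were chosen after the result was seen. Over 40 sets of lines (20 chromosomes in the 9 metastasis and the 6 primary lines), 5 sets had a line far from the rest, from 3 different lines, against 2 sets that chance gives at about 1 in 20.

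Chromosome 15 stood at 0.49 on the log2 scale in Met1 replicate 2, where the other 8 metastasis lines had a mean of 0.00 ± 0.03 (SD), and all 11 windows of 10 Mb lay above their mean. Met3 replicate 3 was far from the other metastasis lines on 3 chromosomes. It stood at -0.26 on chromosome 3 (others -0.02 ± 0.04, 15 of 16 windows below), at -0.16 on chromosome 10 (others 0.11 ± 0.04, 13 of 13 below) and at 0.18 on chromosome 19 (others -0.08 ± 0.04, 7 of 7 above). Chromosome 7 stood at -0.14 in Primary2 replicate 2, against 0.09 ± 0.04 in the other 5 primary lines, with 15 of 15 windows below.

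Chromosome Y was left out of the comparison of chromosomes, and its 2 regions held 322 counts over the 15 libraries. Met1 replicate 1 had 29.1 CPM there, without TMM scaling, Primary3 replicate 1 had 0.98 (3 of 3051139 counts, exact 95% interval 0.20 to 2.87), and Primary3 replicate 2 had 0 of 285633, with an exact 95% interval up to 12.9 (3 counts would be 10.5). The other libraries had between 6.3 and 13.6. The intervals cover counting error only.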

How the results depend on the processing

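Leaving out the 2 shallowest libraries together, and measuring chromosomes by their share of counts or after removal of a trend, were chosen after seeing the data. The call count for rounds 2 and 3 together ran from 7095 to 8932 over 10 alternatives and from 5951 to 8947 when a replicate was left out. The number of chromosomes past the test ran from 10 to 11, and from 8 to 12 when a replicate was left out. Of 634 alternative values of the named regions 633 kept their direction and call, and 1 lost the call. For the 10 named chromosomes 141 of 150 did, and 9 on chromosomes 3 and 10 lost the call with no change of direction. These regions and chromosomes were named because they passed in the same data, so their stability says little about the called regions as a whole.

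A fit of only the groups compared called 1315 regions in round 2 (2480 with all groups), 58 for Met2 against Met1 (1417) and 34 for Primary3 against Primary2 (0), but more in round 3 (6032 against 4059) and for Met3 against Met1 (4476 against 3813). The cause was not tested. The DESeq2 Wald test called 15 regions for the difference between rounds, 44 for Met3 against Met2 and 54 for Primary3 against Primary2, all 0 by edgeR. DESeq2 gave adjusted p for 23680, 29098 and 19808 regions in these contrasts, against 39952 in edgeR, so the counts are not over the same regions. The cause was not tested either. Leaving out a replicate gave 963 to 2810 in round 2, 1483 to 3530 in round 3, 1852 to 3577 for Met3 against Met1 and 475 to 2475 for Met2 against Met1. It gave 0 to 6 for the difference between rounds, 0 to 54 for Met3 against Met2 and 0 to 7 for Primary3 against Primary2. The correlation of the rounds, 0.63, was 0.685 for regions at or above the median signal, 0.597 with no filter, 0.656 with the stricter filter, 0.653 with only the groups compared, 0.62 with chromosome medians removed and 0.551 to 0.669 when a replicate was left out.

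Replicate numbers did not pair the lines. Same-numbered lines correlated between -0.112 and 0.142 in their deviations from the group means, and many correlated best with another number. With the replicate block, 7273 regions were called in rounds 2 and 3 together, 1948 in round 2, 3306 in round 3, 3284 for Met3 against Met1, 1067 for Met2 against Met1 and 0 for the other 3 contrasts. Without the 2 shallowest libraries 8818 regions were called in rounds 2 and 3 together, 4196 in round 3, 3876 for Met3 against Met1 and 1520 for Met2 against Met1. Offsets for GC content, alone or with the block, and the gene list tests with their alternatives were not run. At these depths, spreads and numbers of lines 42 of 100 simulated 2-fold changes were recovered, among regions of at least the median signal and with few regions changed. Depth was not varied alone.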

Other observations

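The score of Met1 lines, the clustering of changed regions, their widths and the tests of chromosome 18 by quartile and against chromosomes of like density were chosen after the result was seen. The bounds for the other tests of chromosomes 18 and 5 and of Met1 were set after those patterns were seen and before the tests were run.

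On a score over changed regions, the round 1 metastasis lines lay between the later metastasis lines and the primary lines. Each line was scored by its mean log2 CPM over regions called higher in a round minus that over regions called lower, using calls from a round to which the line did not belong. With the 2480 regions of round 2, Met3 scored 1.48 ± 0.29, Met1 -0.08 ± 0.43 and Primary3 -1.71 ± 0.15 (SD, n = 3), and Met1 stood 51.1% of the way from Primary3 to Met3. This position was 44.1% over the higher-called and 59.4% over the lower-called regions. With the 4059 regions of round 3, Met2 scored 1.07 ± 0.48, Met1 -0.11 ± 0.39 and Primary2 -1.41 ± 0.11, and Met1 stood at 52.6% (42.2% over higher-called and 62.6% over lower-called regions). Met2 replicate 1 scored 0.53, nearer to Met1 replicate 2 (0.21) than to Met2 replicates 2 and 3 (1.21 and 1.46). With chromosome medians removed the positions over all called regions were 48.3% with round 2 calls and 50.8% with round 3 calls. No Met1 line overlapped the groups beside it, and each exact permutation test gave p = 0.1, the smallest that 3 lines against 3 allow. Without primary lines of round 1, a batch of that round cannot be told apart from this position. The regions were picked for the difference between later metastasis and primary lines. A line with no part in that difference, or with a flat profile, can also fall in the middle, so the position does not show an intermediate state. With round 2 calls the Met1 lines scored 0.015, 0.288 and -0.548 (replicates 1, 2 and 3).

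Changed regions lay in runs along the genome. With chromosome medians removed, 52 of 1734 windows of 1 Mb held more regions called higher than chance placement gives and 45 held more called lower, whereas 20 random placements of the higher calls gave at most 1. Removing the medians leaves shifts of chromosome segments in place, so these were not told apart from changes of single regions. On chromosome 8, 15 of 31 regions between 46000001 and 47000000 were lower in metastasis lines (median log2 fold change -1.66), as were 10 of 15 between 130000001 and 131000000 (-2.12), whereas 10 of 14 between 12000001 and 13000000 were higher (1.73). On chromosome 18, 13 of 27 regions between 44000001 and 45000000 were lower (-2.30), within 304.9 kb around the named peak_45415, and 11 of 17 between 3000001 and 4000000 were higher (2.36). In the 10 Mb window of chromosome 8 from 130000001, with medians kept, Met2 replicate 1 stood at 0.318, above Primary2 replicate 1 (0.294). The other Met2 and Met3 lines were below all primary lines there. On chromosome 1, 10 of 14 regions between 69000001 and 70000000 were higher (2.14). On chromosomes 7 (151000001 to 152000000, -2.03) and 9 (111000001 to 112000000, -1.99), 10 of 16 regions each were lower. The latter lies where chromosome 9 was lower mainly through the Met3 lines. Regions called lower in metastasis lines were wider, with a median of 836 bp against 727 bp for those called higher, and this held in each of 5 bins of mean signal. Uncalled regions had a median of 796 bp, and in the 3 bins of lowest signal they were wider than either.

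Chromosome 18 was lower in all 9 metastasis lines than in all 6 primary lines. The upper quartile of its regional differences lay -0.43 from that of other chromosomes, which argues against a few strongly changed regions as the whole cause, and the difference was -0.42 after a trend on mean signal was removed, which argues against that trend but leaves GC bias untested. A test on the median over uncalled regions (-0.24, against -0.39 over all) was planned first and set aside, because leaving out called regions moves it by construction. All 9 windows of 10 Mb on chromosome 18 (100%) lay below 0, but unevenly, from -0.833 to -0.065. Every window was also lower on chromosome 8 and higher on chromosomes 5, 6 and 13. A copy number difference of the whole chromosome may account for the lower signal, but these signs do not single it out. Coordinated regulation along the chromosome would give the same sign. A trend with region density was first tested by the residual of chromosome 18 (-2.66 SD, between the bounds set for either reading). The 4 chromosomes within 0.5 regions per Mb of it shifted by -0.129 to 0.24. Density and shift, taken per whole chromosome, were unrelated over the other chromosomes (r = -0.02). These values argue against the density of whole chromosomes as the whole cause. Density within chromosomes was not tested. Some windows of 10 Mb with few regions stood high, as on chromosome 17 from 90000001 (27 regions, 0.927, against -0.238 over 241 regions from 30000001). The opposite was seen on chromosome 8 from 130000001 (23 regions, -1.591).

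Chromosome 5 stood at 0.62 in Met2 replicate 1, 0.64 above the mean of the other metastasis lines, which ran from -0.20 to 0.31 (Met3 replicate 1). The test of each line's distance from the others did not single it out, and the pattern was picked by eye. The gap was 0.639 after a trend on mean signal was removed, which argues against that trend but leaves GC bias untested, and 100% of its 16 windows lay above the mean of the other lines, by 0.44 to 0.83. A gain of chromosome 5 in that line is a candidate explanation, and DNA copy number was not measured here.

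In the fit of all groups, more regions were called between Met1 and later metastasis lines than between later groups of the same origin. In fits of only the groups compared, this held clearly for Met3 against Met1 (4476 regions). Met2 against Met1 (58) was then near Primary3 against Primary2 (34), with 0 for Met3 against Met2. The weak library Met1 replicate 1 was not the whole cause, since 3577 regions of Met3 against Met1 were called without it, nor were chromosome-wide shifts, with 3916 called after chromosome medians were removed. A sequencing or culture batch of round 1 cannot be told apart from the round, because 0 primary lines of round 1 were among the samples. A change along the transplantation rounds also stays open, as untested.

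Other splits of the libraries were fitted in the same way. For rounds 2 and 3 together, 1 of 40 splits drawn from 200, the real one, gave as many as 8080 regions, and the highest other gave 375. Random labels on independent lines would thus seldom give so many, and the share of 0.025 is the smallest that 40 splits allow. Chance is not excluded, because which line descended from which is not known and the lines may not be independent. The difference between rounds called 0 regions, so that 40 of 40 splits gave as many or more (up to 2) by construction, and the splits say nothing there. With 3 lines against 3 there are 10 splits, too few for a share under 0.05. The real value was 2480 in round 2 (highest other 5), 4059 in round 3 (0), 3813 for Met3 against Met1 (0), 1417 for Met2 against Met1 (455), 0 for Met3 against Met2 (4) and 0 for Primary3 against Primary2 (0). As many regions as the real split were given by 1 of 10 splits in the first 4 of these and, by construction with a count of 0, by 10 of 10 in the last 2.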
